A study of Vitis vinifera with 12 samples.

How the data were processed

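RNA sequencing was done on berries of the grape cultivars Kyoho and Shine-muscat, with 12 libraries in 4 groups of 3: control and treated berries of each cultivar. Groups were taken from the sample titles, in which treated means Botrytis cinerea. The series text counts each berry as a replication, and nothing else is given about how independent the replicates were. The replicate numbers are not stated to pair libraries. Alignment was done with HISAT, per the submitters' processing notes. Its version, the genome build, the counter, the treatment of strand and of reads with several matches, and the authors' test are not given in the sources used here.

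The deposited table gives a read count per gene and library as whole numbers, per the file headers. It also gives FPKM per library and per group, which the authors scaled by gene length and library size. For pairs of groups of the same cultivar or the same label it gives the authors' p-value and adjusted p-value, per the file headers. Only these were read from the authors' comparisons. Gene identifiers, coordinates and descriptions (best Swiss-Prot hits) were used as deposited, and 24723 genes had a description while 7726 had none. The table held 32449 genes, of which 605 were loci outside the reference gene models. The gene sequences were not used here. The supplied gene table belongs to another assembly and was not used.

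Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at a minimum count of 10, leaving 19530 genes (560 outside the reference models) and removing 12919. The tested genes held 99.97% to 99.99% of each library's counts, and the 10 genes with most counts held 8.614% to 15.07%. Library sizes were scaled by TMM. All 12 libraries were fitted together with 1 mean per group (8 residual degrees of freedom) by the robust quasi-likelihood method. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05 in each comparison. Comparisons were treated minus control in each cultivar, the difference between these responses, and Shine-muscat minus Kyoho in control and in treated berries. Tests were two-sided. The standard error of a log2 fold change was its size divided by the square root of the F statistic. CPM are counts per library total scaled by TMM.

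The deepest library had 52266554 counts and the shallowest 32671972. A count of 0 allows up to 3 counts, or 0.0552 to 0.0974 CPM depending on the library. Where a group had no counts a fold was computed against a floor of 3 counts over the group. Where it had 1 to 3 counts the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only.

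Before the data were examined, 25 gene lists were defined by words in the descriptions, as were the comparisons, the alternatives and the rule for naming genes. The list of PR proteins also caught 4 "Protein GPR107" genes, 3 of them tested. Lists of organelle-type transcripts and of genes on in 1 cultivar were chosen after their values were seen. Lists were tested with limma 3.58.1 by camera with a preset correlation of 0.01. Alternatives were an estimated correlation and fry, which tests whether genes of a list move 1 way on balance, or in its mixed form either way, and compares them with no other genes. Adjusted p-values of list tests cover the 25 lists of a comparison. Overlaps were tested with Fisher's exact test.

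For each treatment comparison the rule took the 5 largest rises and 5 largest falls among described, changed genes with a mean log2 CPM of at least 2 and with all 3 treated libraries on 1 side of all 3 controls. It added the risen and the fallen member with the smallest p of each list (mean log2 CPM of at least 1). For the difference between responses it took the 5 smallest p in each direction. For each cultivar comparison it took the 4 largest in each direction and members of the flavonoid, terpenoid and stilbene lists. The rule gave 59 genes in Kyoho and 58 in Shine-muscat. Of these the text prints the largest changes, the members of lists that camera called, and the chitin receptors, a subset chosen after the values were seen.

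Alternatives were DESeq2 size factors (RLE) and upper-quartile factors in place of TMM, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2(FPKM + 1) for genes at an FPKM of at least 1 in 3 libraries, no filter, a filter at 1 CPM in every library of a group, fits of only the groups compared, a 2-fold threshold, the replicate number as a block, and leaving out each library. Scaling by library totals only was added after seeing the data. A smaller pseudocount was planned only for a table without counts and was not run. Simulated counts for 19530 genes were used to test the fit. Of these, 100 genes changed 2-fold and 100 changed 4-fold, as many up as down, all with a mean above 1 CPM. In the Kyoho comparison the fit recovered 77% of genes changed 2-fold and 95% of genes changed 4-fold, with 3.37% false calls. For the difference between responses it recovered 39% and 86%, with 3.10% false calls. Far more genes were called in the data. The simulation thus tests neither scaling when most genes change nor recovery at low counts. In a simulation of 21 lists, camera called the 1 list with changed genes and 0 of the others, as did camera with an estimated correlation and fry. Each gene was drawn independently there, so the simulation does not test lists of correlated genes.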

Results

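Gene expression was measured by RNA sequencing of mature berries of 2 grape cultivars, the dark-berried Kyoho and the green-yellow Shine-muscat. Each cultivar gave 3 libraries labelled control and 3 labelled as treated with Botrytis cinerea, the fungus of grey mould. The 12 libraries thus formed 4 groups. The series text describes a chitosan spray of 15% (w/v) at 15 kDa with water as control, spores 1 day later, and incubation at 25 °C and 95% relative humidity. Chitosan, a polymer derived from chitin, is used to induce plant defences. The protocol field names chitosan, with another figure, for all 12 libraries. Which libraries were sprayed with it is therefore open, and "control" and "treated" are the labels of the titles throughout. The series title asks how chitosan acts against the fungus on berries.

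Total counts per library ranged from 32671972 to 41906325 in Kyoho control and from 43598355 to 52266554 in Kyoho treated. They ranged from 43539783 to 47551838 in Shine-muscat control and from 44653617 to 47220130 in Shine-muscat treated. Of 32449 genes in the table, 19530 had enough counts to be tested. Expression is given in CPM as mean ± SD with n = 3 libraries per group, and log2 fold changes are given with ± their standard error. Gene identities are the best Swiss-Prot hits deposited with the table. Coordinates are those of the table, whose genome build is not given in the sources used here. The series text counts each berry as a replication, and p-values measure the spread between these libraries. Libraries of 1 group correlated at r = 0.981 to 0.989 across genes, which are not independent replicates. The first principal component held 61.7% of the variance. It ran from Kyoho control (-173.3 ± 2.6) over Kyoho treated (-14.8 ± 7.2) and Shine-muscat treated (21.6 ± 17.9) to Shine-muscat control (166.4 ± 3.8). The second held 23.4% and parted Kyoho treated (-104.9 ± 5.6) from Shine-muscat treated (104.4 ± 14.1).

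**Figure D1:**
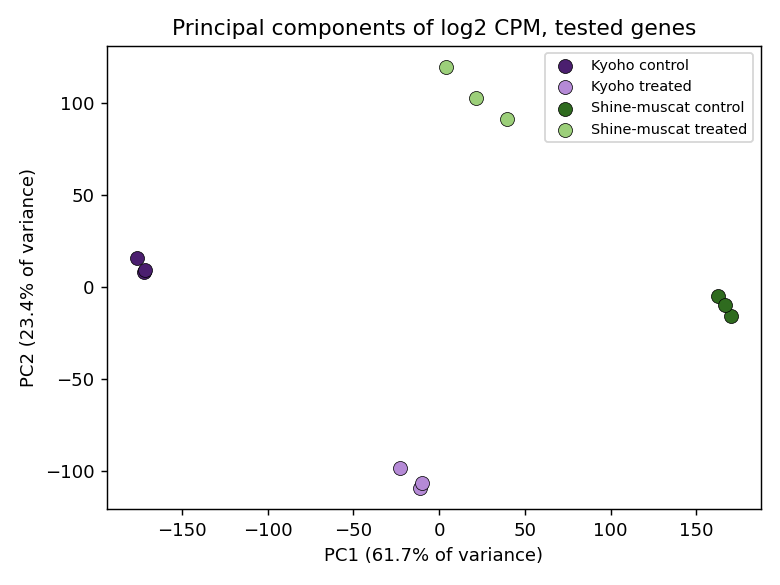
Principal components of log2 CPM over the 19530 tested genes, with 1 point per library coloured by group. The first axis (61.7% of the variance) has the control libraries of both cultivars at its ends, and the second (23.4%) parts the treated libraries of Kyoho from those of Shine-muscat.

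Pigment genes were read first, since they describe whether libraries go with their cultivar label. The leucoanthocyanidin dioxygenase gene VIT_202s0025g04720 (chromosome 2, 4282027 to 4284085), of the anthocyanin pathway, was at 82 ± 16.8 CPM in Kyoho control and 24.3 ± 1.54 CPM in Kyoho treated berries. It was at 1.11 ± 0.155 CPM in Shine-muscat control and 7.91 ± 1.17 CPM in Shine-muscat treated berries. Summed over the flavonoid and anthocyanin list, expression was 1043 ± 127, 747.6 ± 82.1, 730.6 ± 47 and 1320 ± 105 CPM in the same order, so the sum did not separate the cultivars. An anthocyanidin 3-O-glucosyltransferase 6 hit, VIT_203s0017g02120 (chromosome 3, 18793856 to 18805971), did not either, at 120 ± 16.8, 2.47 ± 1.7, 0.021 ± 0.00195 and 26.7 ± 11.1 CPM.

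Genes that did separate them were chosen after their values were seen. A glutathione S-transferase F12 hit, VIT_204s0079g00690 (chromosome 4, 11504521 to 11507410), was at 102 ± 38.9 CPM in Kyoho control and 27.4 ± 6.43 CPM in Kyoho treated berries. It had 0 counts in all 6 Shine-muscat libraries, where 0 counts allow at most 0.0692 CPM in a library. The MYB113-type factor VIT_202s0033g00410 (chromosome 2, 14239584 to 14240983) was at 2.82 ± 1.03 and 2.46 ± 0.748 CPM in the Kyoho groups and likewise had 0 counts in Shine-muscat. In all, 5 genes were at a mean of at least 10 CPM in both Kyoho groups with at most 3 counts in each Shine-muscat group, and 5 showed the converse.

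In Kyoho, most tested stilbene synthase, phenylpropanoid entry and peroxidase or laccase genes fell in the libraries labelled treated, while of the immune receptors of the NB-LRR type more rose than fell and 189 of 398 did not pass. As lists, these 4 were at adjusted p = 0.253 with an estimated correlation. Stilbene synthases, which make resveratrol, summed to 11760 ± 2060 CPM in control and 205.2 ± 114 CPM in treated berries. Of 41 tested stilbene synthase genes, 39 fell and 0 rose, with a median log2 fold change of -5.34 (-5.13 with genes without counts in a group at their bound). The entry enzymes of the phenylpropanoid pathway, which supply stilbenes, flavonoids and lignin, fell in 24 of 29 and rose in 2 (median -4.41). NB-LRR receptors, which act inside the cell, rose in 170 of 398 and fell in 39 (median 0.73, or 0.72 at the bound). Across all genes 5672 rose and 5675 fell, 58.1% of those tested.

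The hormone and signalling lists were mixed. Of them, camera with an estimated correlation called only jasmonate biosynthesis and ethylene, both lower (adjusted p = 0.0474 each). Jasmonate biosynthesis fell in 20 of 30 genes and rose in 2 (median -2.65). Ethylene synthesis and response fell in 52 of 102 and rose in 16 (median -0.69). WRKY factors, transcription factors of the defence response, fell in 33 of 53 and rose in 13 (median -1.66). Salicylate signalling fell in 12 of 29 and rose in 8, with a median of -0.03 that turned to 0.08 with upper-quartile factors and 0.16 with library totals. Chitin and LysM receptors fell in 7 of 15 and rose in 5 (median -0.34). Abscisic acid genes fell in 5 of 17 and rose in 6, with a median of 0.23, a mean of -0.3 and a list test directed up. Jasmonate signalling fell in 6 of 15 and rose in 7, with a median of 0.31, a mean of -0.53 and a list test directed down.

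Class III peroxidases and laccases fell in 54 of 80 and rose in 6 (median -4.22). Chitinases and glucanases, which cut fungal walls, fell in 32 of 58 and rose in 12 (median -0.84). Antioxidant enzymes fell in 47 of 91 and rose in 21 (median -0.59). Lignin genes fell in 17 of 36 and rose in 7 (median -0.36), and flavonoid genes fell in 13 of 25 and rose in 3 (median -0.68). PR-1, PR-5 and PR-10 proteins fell in 18 of 37 and rose in 10 (median -0.43). Terpenoid genes fell in 14 of 36 and rose in 7, with a median of -0.11 that became 0 with library totals. Cytosolic ribosomal proteins fell in 135 of 197 and rose in 8 (median -0.54). Sugar genes fell in 17 of 37 and rose in 13, and wall-loosening genes fell in 50 of 145 and rose in 44. Their medians of -0.01 and -0.05 turned to 0.1 and 0.06 with upper-quartile factors and to 0.17 and 0.14 with library totals. Heat shock proteins fell in 24 of 71 and rose in 18 (median -0.29), a balance that turned to 19 and 21 with library totals.

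No list of tissue markers or photosynthesis genes was called by camera, with adjusted p = 0.148 for seed, 0.197 for skin, 0.905 for vascular markers and 0.287 for photosynthesis. Fry called seed (adjusted p = 9.48e-05) and skin (1.16e-05) markers lower, but not vascular markers (0.891) or photosynthesis (0.0949). Seed markers fell in 7 of 16 and rose in 2 (median -1.05, or -1.93 without Kyoho treated replicate 2), with sums of 127.3 ± 32.9 CPM in control and 40.69 ± 1.99 CPM in treated berries. Skin and cuticle markers fell in 22 of 52 and rose in 9 (median -0.19), with sums of 715 ± 61.3 and 508.1 ± 29.5 CPM. Vascular markers fell in 5 of 20 and rose in 5, with sums of 296.5 ± 2.95 and 581.6 ± 119 CPM, a median of 0.03 (0 with DESeq2 size factors), a mean of -0.38 and a list test directed up. Photosynthesis genes fell in 11 of 49 and rose in 19 (median 0.48). Organelle-type transcripts, a list chosen after the values were seen, summed to 730.5 ± 182 CPM in control and 329 ± 12.4 CPM in treated libraries.

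Adjusted over the list alone, 40 stilbene synthase, 26 phenylpropanoid entry, 34 chitinase and glucanase, 21 jasmonate biosynthesis, 25 heat shock, 14 photosynthesis and 139 ribosomal protein genes fell. Likewise adjusted over the list alone, 166 NB-LRR genes rose and 38 fell, and 45 wall-loosening and 20 photosynthesis genes rose. The other counts were those over all genes.

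The largest falls were near-complete losses of transcripts that control berries held at moderate levels. The tetraketide alpha-pyrone reductase VIT_213s0067g00460 (chromosome 13_random, 271934 to 274168) was 626-fold higher in control than in treated libraries (95% counting interval 214 to 3040), at 12.6 ± 1.16 against 0.0202 ± 0.00177 CPM. A Kunitz trypsin inhibitor, VIT_217s0119g00150 (chromosome 17, 13578010 to 13588416, log2 fold change -7.74 ± 0.66), and laccase-23, VIT_200s0481g00020 (unplaced sequence Un, 30209255 to 30211334, log2 fold change -7.46 ± 0.82), also fell. So did a pair of auxin-binding protein ABP19a genes, VIT_207s0005g05930 (chromosome 7, 10376424 to 10377236, log2 fold change -7.44 ± 0.34) and VIT_207s0005g05920 (chromosome 7, 10351085 to 10351718, log2 fold change -7.43 ± 0.61). Without Kyoho treated replicate 1 the Kunitz inhibitor was at -9, and without replicate 3 the second ABP19a gene was at -8.11. The largest rises included the water channel aquaporin PIP2-4, VIT_208s0040g01890 (chromosome 8, 12986201 to 12988395), at 10.8 ± 1.82 CPM in control and 253 ± 59.5 CPM in treated libraries (log2 fold change 4.54 ± 0.37, adjusted p = 2.24e-06). A heavy metal-associated isoprenylated protein, VIT_205s0020g02690 (chromosome 5, 4417324 to 4421347, log2 fold change 4.97 ± 0.57), and asparagine synthetase, VIT_206s0004g06830 (chromosome 6, 7527838 to 7531543, log2 fold change 4.53 ± 0.48), rose. Glycerol kinase, VIT_209s0002g07860 (chromosome 9, 8307448 to 8310345, log2 fold change 4.29 ± 0.42), and an L-tryptophan-pyruvate aminotransferase of auxin synthesis, VIT_200s0225g00230 (unplaced sequence Un, 14754246 to 14757498, log2 fold change 4.24 ± 0.42), rose as well.

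Within the enzyme lists, stilbene synthase 5 fell, VIT_216s0100g00830 (chromosome 16, 16335550 to 16338071), at 48.9 ± 5.89 CPM in control and 1.04 ± 0.0481 CPM in treated libraries (log2 fold change -5.55 ± 0.43, adjusted p = 1.54e-06). The 4-coumarate-CoA ligase-like gene VIT_218s0001g00290 (chromosome 18, 1253932 to 1257727, log2 fold change -3.12 ± 0.2) fell. Another, VIT_202s0109g00250 (chromosome 2, 12710013 to 12716043, log2 fold change 0.79 ± 0.27), rose, a call lost without Kyoho control replicate 1 (adjusted p = 0.0867) or 3 (0.0667) or Kyoho treated replicate 2 (0.0909) or 3 (0.0631). Leucoanthocyanidin dioxygenase, VIT_202s0025g04720 (chromosome 2, 4282027 to 4284085, log2 fold change -1.75 ± 0.15), fell and flavonoid 3'-monooxygenase, VIT_217s0000g07200 (chromosome 17, 8011519 to 8014480, log2 fold change 1.91 ± 0.21), rose. The basic vacuolar glucanase VIT_205s0077g01150 (chromosome 5, 894812 to 896133), at 3990 ± 208 CPM in control and 1140 ± 14.6 CPM in treated libraries (log2 fold change -1.8 ± 0.15, adjusted p = 7.21e-07) fell. Glucan endo-1,3-beta-glucosidase 3, VIT_212s0059g01320 (chromosome 12, 6263832 to 6267156, log2 fold change 3.1 ± 0.27), rose. The 12-oxophytodienoate reductase VIT_218s0041g02080 (chromosome 18, 27211258 to 27214786, log2 fold change -2 ± 0.17) fell and a 13S-lipoxygenase, VIT_206s0004g01510 (chromosome 6, 1875142 to 1882102, log2 fold change 2.66 ± 0.44), rose, both of jasmonate synthesis. Peroxidase 12, VIT_218s0072g00160 (chromosome 18, 19199384 to 19202595, log2 fold change -3.04 ± 0.28), fell and peroxidase 31, VIT_214s0066g01850 (chromosome 14, 28160794 to 28161995, log2 fold change 2.14 ± 0.27), rose. Glutathione reductase, VIT_207s0141g00390 (chromosome 7, 228811 to 236423, log2 fold change -2.44 ± 0.15), fell and a glutathione S-transferase, VIT_219s0093g00190 (chromosome 19, 16626323 to 16628329, log2 fold change 1.77 ± 0.17), rose.

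Among regulators, ethylene-responsive factor 1A fell, VIT_202s0234g00130 (chromosome 2, 177838 to 178960), at 629 ± 58.7 CPM in control and 58 ± 5 CPM in treated libraries (log2 fold change -3.44 ± 0.15, adjusted p = 1.23e-08). ERF003, VIT_204s0008g06000 (chromosome 4, 5694467 to 5698758, log2 fold change 1.99 ± 0.18), rose. WRKY 65, VIT_210s0003g01600 (chromosome 10, 3008584 to 3010705, log2 fold change -2.56 ± 0.12), fell and WRKY 32, VIT_204s0008g06600 (chromosome 4, 6569701 to 6576794, log2 fold change 2.57 ± 0.21), rose. Of LysM domain receptor-like kinase 3 hits, of a family that binds chitin, VIT_213s0019g04550 (chromosome 13, 5986256 to 5987899, log2 fold change -1.86 ± 0.12) fell and VIT_209s0002g03440 (chromosome 9, 3105637 to 3116524, log2 fold change 1.11 ± 0.17) rose. The immune receptor hits RGA4, VIT_215s0024g00400 (chromosome 15, 581224 to 586019, log2 fold change -1.88 ± 0.15), and TMV resistance protein N, VIT_201s0026g01110 (chromosome 1, 10108792 to 10118183, log2 fold change 1.83 ± 0.14), fell and rose respectively. Ribosomal protein L10, VIT_206s0004g08260 (chromosome 6, 9072567 to 9076932, log2 fold change -1.58 ± 0.15), fell and L19-2, VIT_207s0005g00840 (chromosome 7, 3456003 to 3459575, log2 fold change 0.73 ± 0.12), rose.

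The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The groups of 12494 of the 19530 genes did not overlap, against 10% by chance, and of 5881 genes that changed at least 2-fold 2464 rose and 3417 fell. With library totals as the only scaling 7191 rose and 4535 fell, with upper-quartile factors 6606 and 5002, and with limma on log2 FPKM 6711 and 4030. The balance went the other way with DESeq2 size factors (5212 rose and 6063 fell) and the DESeq2 Wald test (5372 and 6174). Library totals moved the median of all genes by 0.188, FPKM by 0.154 and upper-quartile factors by 0.11. The authors' deposited table calls 9788 genes, of which 9455 were called here. With the preset correlation camera called 11 of 25 lists, NB-LRR higher (adjusted p = 0.000391) and 10 lower, the smallest adjusted p being 3.22e-14 for stilbene synthase. Splits that mixed the groups, which keep part of the difference between them, gave 7 to 11 lists by the same setting. List tests without single libraries or with the replicate block used only the preset correlation. With an estimated correlation jasmonate biosynthesis and ethylene were still called, narrowly, at adjusted p = 0.0474. The others were not, with adjusted p = 0.253 with an estimated correlation for stilbene synthase, phenylpropanoid entry, NB-LRR and class III peroxidases and laccases. It was 0.201 for chitinases, 0.224 for WRKY factors, 0.325 for flavonoids, 0.335 for antioxidants and 0.59 for ribosomal proteins.

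The flavonoid call (adjusted p = 0.0434) was lost without Kyoho control replicate 3 (0.0713) or Kyoho treated replicate 2 (0.0889). Lignin (0.0532) passed without Kyoho control replicate 2 (0.0212), Kyoho treated replicate 1 (0.0423) or Kyoho treated replicate 3 (0.0415). Stilbene synthases, laccases and glutathione S-transferases are families of near-identical copies. How reads shared between copies were counted is not given in the sources used here, so values of single members are uncertain.

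**Figure D2:**
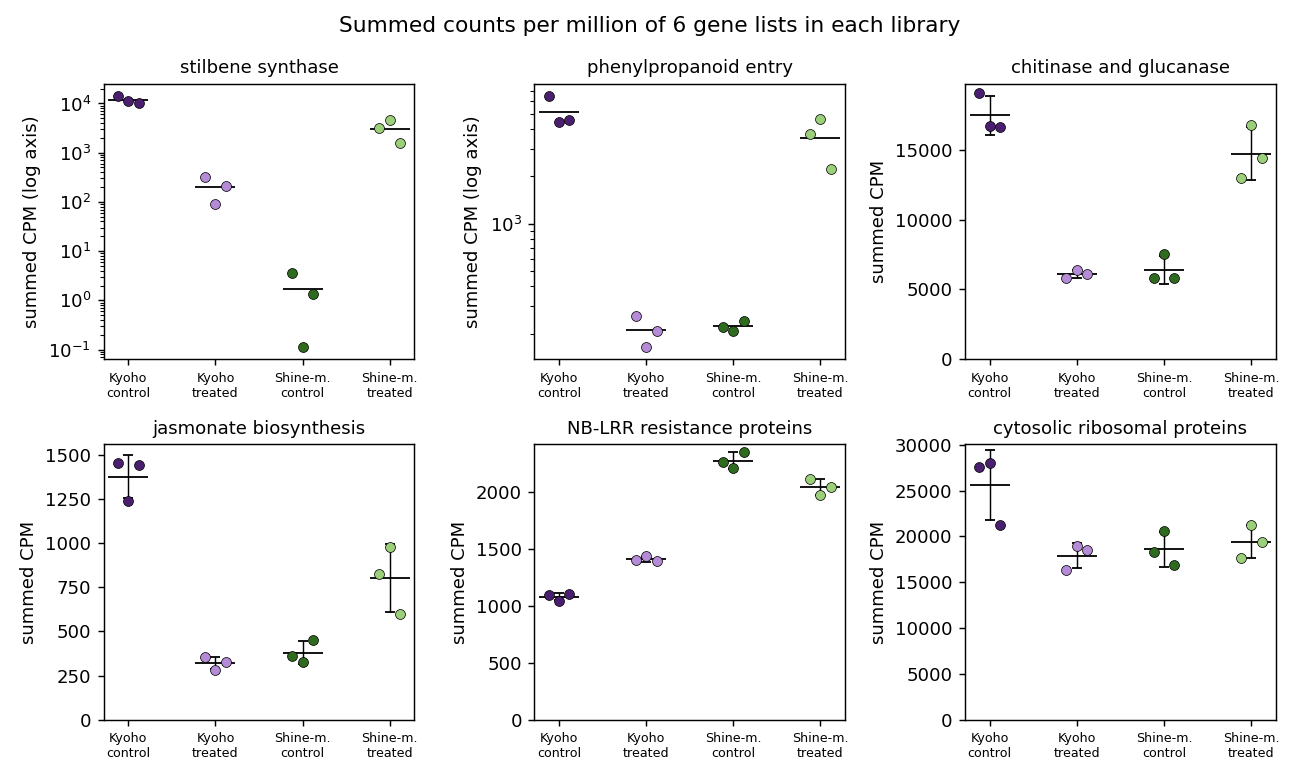
Summed CPM of 6 gene lists, 1 point per library, with the mean of each group of 3 as a bar and its SD as an error line in the 4 panels with linear axes; the stilbene synthase and phenylpropanoid panels have log axes and show the mean only. Stilbene synthase sums were 11760 in Kyoho control, 205.2 in Kyoho treated, 1.677 in Shine-muscat control (0.7395 without replicate 1) and 3089 in Shine-muscat treated libraries.

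In Shine-muscat, most tested stilbene synthase, phenylpropanoid entry and peroxidase or laccase genes rose in the libraries labelled treated, while 288 of 398 NB-LRR receptors did not pass. As lists, these were at adjusted p = 0.0824, 0.0833, 0.255 and 0.287 with an estimated correlation. Stilbene synthases summed to 1.677 ± 1.74 CPM in control and 3089 ± 1500 CPM in treated berries, and to a mean of 0.7395 CPM in control without Shine-muscat control replicate 1. All 41 tested genes rose, with a median log2 fold change of 10.3 (9.54 with genes without counts in a group at their bound, and 10.91 without that library). Phenylpropanoid entry enzymes rose in 24 of 29 and fell in 1 (median 8.39, or 5.55 at the bound, and 7.79 without Shine-muscat treated replicate 2). Class III peroxidases and laccases rose in 46 of 80 and fell in 7 (median 3.97, or 2.74 at the bound, and 4.57 without Shine-muscat control replicate 3). Across all genes 3881 rose and 2924 fell, 34.8% of those tested.

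PR-1, PR-5 and PR-10 proteins rose in 19 of 37 and fell in 5 (median 0.79). Chitinases and glucanases rose in 19 of 58 and fell in 10 (median 0.83), and antioxidant enzymes rose in 36 of 91 and fell in 12 (median 0.28). WRKY factors rose in 27 of 53 and fell in 7 (median 0.69). Jasmonate biosynthesis rose in 16 of 30 and fell in 3 (median 1.03, or 0.94 at the bound), and ethylene rose in 44 of 102 and fell in 21 (median 0.31). Flavonoid genes rose in 10 of 25 and fell in 1 (median 0.64), lignin genes rose in 14 of 36 and fell in 6 (median 0.44), and terpenoid genes rose in 10 of 36 and fell in 2 (median 0.37). Abscisic acid genes rose in 5 of 17 and fell in 0 (median 0.15), and chitin and LysM receptors rose in 6 of 15 and fell in 2 (median 0.2). Jasmonate signalling rose in 6 of 15 and fell in 3, with a median of 0.01 that turned to -0.02 with DESeq2 size factors, -0.08 with upper-quartile factors and -0.07 with library totals. Salicylate signalling rose in 7 of 29 and fell in 5, which became 6 and 7 with upper-quartile factors and 5 and 8 with library totals (median 0).

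NB-LRR receptors rose in 40 of 398 and fell in 70 (median -0.15), heat shock proteins rose in 4 of 71 and fell in 24 (median -0.22), and photosynthesis genes rose in 2 of 49 and fell in 11 (median -0.41). Sugar genes rose in 14 of 37 and fell in 8 (median 0.1). Wall-loosening genes rose in 35 of 145 and fell in 37, with a median of -0.01, a mean of 0.79 and a list test directed down. Cytosolic ribosomal proteins rose in 13 of 197 and fell in 4 (median 0.09), which became 10 and 12 with upper-quartile factors and 11 and 12 with library totals. Skin and cuticle markers rose in 16 of 52 and fell in 5, with a median of 0.01 that became 0 with each other scaling, and with sums of 496.8 ± 18.9 CPM in control and 552.9 ± 35.7 CPM in treated berries. Seed markers rose in 3 of 16 and fell in 2 (median 0.48), with sums of 65.04 ± 34.4 and 45.43 ± 12.4 CPM. Vascular markers rose in 2 of 20 and fell in 4, with sums of 987.4 ± 190 and 629.4 ± 126 CPM, a median of -0.13, a mean of 0.04 and a list test directed down. Fry called skin markers higher (adjusted p = 0.000296), but not seed (0.0518) or vascular (0.736) markers. Organelle-type transcripts summed to 195.8 ± 4.93 and 199.3 ± 3.6 CPM.

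Adjusted over the list alone, 25 phenylpropanoid entry, 15 lignin, 21 chitinase, 20 PR, 17 jasmonate biosynthesis, 28 WRKY, 40 antioxidant, 50 peroxidase and laccase, 39 wall-loosening and 18 skin genes rose. Falls adjusted over the list alone were 3 flavonoid, 7 PR, 4 jasmonate signalling, 7 salicylate, 23 ethylene, 8 peroxidase and laccase, 40 wall-loosening, 10 sugar and 3 vascular genes. Also adjusted over the list alone, NB-LRR genes rose in 38 and fell in 65, photosynthesis genes rose in 1 and fell in 7, and ribosomal protein genes rose in 2 and fell in 0. The other counts were those over all genes.

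The largest rises were mostly lower bounds against control libraries without counts, with a floor of 3 counts over the group. Stilbene synthase 5, VIT_216s0100g00780 (chromosome 16, 16276379 to 16278547), was at least 5200-fold higher, reaching 108 ± 62.5 CPM. Stilbene synthase 4 hits VIT_216s0100g01040 (chromosome 16, 16511136 to 16512898) and VIT_216s0100g00880 (chromosome 16, 16366812 to 16368417) were at least 3050-fold and 1280-fold higher. Pectinesterase 2, VIT_206s0009g02560 (chromosome 6, 15304313 to 15306396), was at least 3490-fold higher. An isoflavone 2'-hydroxylase hit, VIT_207s0129g00800 (chromosome 7, 16015531 to 16017755), was 11400-fold higher (95% counting interval 3150 to 93900) at 158 ± 33.7 CPM. Its 2 control counts lay in replicate 1, without which it was at least 4830-fold higher, and it was 7540-fold higher without control replicate 3. The largest falls included GEM-like protein 4, VIT_210s0071g00320 (chromosome 10, 16617690 to 16620117), at 60.4 ± 15.1 CPM in control and 3.26 ± 1.35 CPM in treated libraries (log2 fold change -4.21 ± 0.31, adjusted p = 1.82e-06). The wall-loosening expansin-A15, VIT_217s0053g00990 (chromosome 17, 16771843 to 16774202, log2 fold change -3.91 ± 0.35), and a xyloglucan endotransglucosylase/hydrolase, VIT_211s0052g01270 (chromosome 11, 18990291 to 18994128, log2 fold change -3.66 ± 0.41), fell. Protein EXORDIUM, VIT_218s0001g06020 (chromosome 18, 4594155 to 4595268, log2 fold change -3.83 ± 0.41), and a serine/threonine-protein kinase, VIT_207s0031g00480 (chromosome 7, 16701290 to 16704781, log2 fold change -3.66 ± 0.36), fell as well.

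Within the phenylpropanoid lists, stilbene synthase 4 hit VIT_216s0100g00860 (chromosome 16, 16349897 to 16351446) was 896-fold higher in treated libraries (95% counting interval 248 to 7410). Its 2 control counts lay in replicate 1, without which it was at least 381-fold higher, and it was 595-fold higher without control replicate 3. The 4-coumarate-CoA ligase-like 9 hit VIT_217s0000g01790 (chromosome 17, 1326450 to 1333019, log2 fold change 2.62 ± 0.17) rose. Another, VIT_214s0171g00300 (chromosome 14, 26130448 to 26133199, log2 fold change -0.72 ± 0.22), fell, a call lost without Shine-muscat control replicate 1 (adjusted p = 0.0831) or 3 (0.0579) or Shine-muscat treated replicate 1 (0.0796). Caffeic acid 3-O-methyltransferase 1 of lignin synthesis rose, VIT_216s0098g00850 (chromosome 16, 21165470 to 21178109), at 9.31 ± 1.12 CPM in control and 102 ± 16.1 CPM in treated libraries (log2 fold change 3.45 ± 0.19, adjusted p = 1.47e-07). Cinnamoyl-CoA reductase 1, VIT_206s0004g07130 (chromosome 6, 7898099 to 7902334, log2 fold change -0.75 ± 0.1), fell. Anthocyanidin reductase, which makes flavan-3-ols, rose, VIT_215s0046g01160 (chromosome 15, 18200951 to 18202757), at 0.065 ± 0.0795 CPM in control and 109 ± 13.5 CPM in treated libraries (log2 fold change 10.56 ± 0.45, adjusted p = 1.08e-07). Of its 10 control counts 8 lay in replicate 1, without which the log2 fold change was 12.1. Flavonoid 3'-monooxygenase, VIT_209s0002g01090 (chromosome 9, 829306 to 832222, log2 fold change -0.77 ± 0.22), fell, a call lost without Shine-muscat control replicate 1 (adjusted p = 0.0931) or Shine-muscat treated replicate 1 (0.0555) or 3 (0.053).

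Among other enzymes and PR proteins, osmotin-like protein OSM34 rose, VIT_202s0025g04340 (chromosome 2, 3824931 to 3825899), at 111 ± 26 CPM in control and 1650 ± 553 CPM in treated libraries (log2 fold change 3.89 ± 0.25, adjusted p = 2.88e-07). Thaumatin-like protein 1, VIT_204s0023g03550 (chromosome 4, 20090718 to 20092702, log2 fold change -1.32 ± 0.33), fell. Glucan endo-1,3-beta-glucosidase 13, VIT_219s0090g01070 (chromosome 19, 7150398 to 7152652, log2 fold change 4.79 ± 0.22), rose and 11, VIT_211s0016g05560 (chromosome 11, 4949398 to 4955000, log2 fold change -0.65 ± 0.09), fell. A 12-oxophytodienoate reductase, VIT_218s0122g01170 (chromosome 18, 802997 to 806128, log2 fold change 1.18 ± 0.12), rose and a 9S-lipoxygenase, VIT_205s0020g03170 (chromosome 5, 4934698 to 4939578, log2 fold change -1.32 ± 0.21), fell. Peroxidase 15, VIT_206s0004g01180 (chromosome 6, 1261464 to 1263622, log2 fold change 5.32 ± 0.41), rose (4.72 without Shine-muscat treated replicate 2) and peroxidase 31, VIT_214s0066g01850 (chromosome 14, 28160794 to 28161995, log2 fold change -3.39 ± 0.29), fell. Of glutathione S-transferases, VIT_219s0093g00310 (chromosome 19, 16876881 to 16878309, log2 fold change 3.77 ± 0.29) rose and VIT_219s0093g00190 (chromosome 19, 16626323 to 16628329, log2 fold change -1.09 ± 0.17) fell. Geraniol 8-hydroxylase of terpenoid synthesis, VIT_202s0025g04890 (chromosome 2, 4403949 to 4404958, log2 fold change 3.95 ± 0.22), rose. A 1-deoxy-D-xylulose-5-phosphate synthase, VIT_200s0218g00110 (unplaced sequence Un, 14030379 to 14035523, log2 fold change -0.67 ± 0.21), fell, a call lost without Shine-muscat control replicate 2 (adjusted p = 0.0626) or 3 (0.0564) or Shine-muscat treated replicate 1 (0.0829) or 2 (0.0725).

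Among regulators, ethylene-responsive factor 1A rose, VIT_202s0234g00130 (chromosome 2, 177838 to 178960), at 46.2 ± 6.57 CPM in control and 363 ± 50.7 CPM in treated libraries (log2 fold change 2.97 ± 0.14, adjusted p = 5.66e-08). ERF025, VIT_216s0100g00400 (chromosome 16, 15837953 to 15838931, log2 fold change -2.1 ± 0.19), fell. WRKY 65, VIT_210s0003g01600 (chromosome 10, 3008584 to 3010705, log2 fold change 1.69 ± 0.12), rose and WRKY 48, VIT_205s0077g00730 (chromosome 5, 529068 to 532146, log2 fold change -0.86 ± 0.14), fell. Of the LysM kinases, VIT_213s0019g04550 (chromosome 13, 5986256 to 5987899, log2 fold change 1.63 ± 0.12) rose and VIT_209s0002g03440 (chromosome 9, 3105637 to 3116524, log2 fold change -0.96 ± 0.17) fell. The immune receptor hit RGA1, VIT_201s0011g01110 (chromosome 1, 965794 to 975031, log2 fold change 2.14 ± 0.19), rose and the RPP13-like protein 1, VIT_212s0035g00750 (chromosome 12, 20218476 to 20220934, log2 fold change -2.19 ± 0.19), fell. A class II small heat shock protein, VIT_204s0008g01520 (chromosome 4, 1224823 to 1225354, log2 fold change 1.33 ± 0.28), rose and heat shock factor HSF30, VIT_204s0008g01110 (chromosome 4, 921542 to 923980, log2 fold change -3.01 ± 0.35), fell. The Rubisco small chain, VIT_211s0052g00810 (chromosome 11, 18369182 to 18375959, log2 fold change 0.39 ± 0.1), rose and a photosystem II polypeptide, VIT_219s0027g00200 (chromosome 19, 18708595 to 18710098, log2 fold change -1.02 ± 0.19), fell.

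In the same edgeR test the groups of 9575 of 19530 genes did not overlap, against 10% by chance, and of 3361 that changed at least 2-fold 2270 rose and 1091 fell. With upper-quartile factors 3408 rose and 3862 fell, with library totals 3341 and 3669, and with limma on log2 FPKM 2954 and 3579. With DESeq2 size factors 3704 rose and 3153 fell. The authors' deposited table calls 5058 genes, of which 4877 were called here. Camera with the preset correlation called 15 of 25 lists, 12 higher and 3 lower (NB-LRR, heat shock and photosynthesis), the smallest adjusted p being 2.38e-46 for stilbene synthase. Splits that mixed the groups, which keep part of the difference between them, gave 6 to 11 lists. With an estimated correlation camera called 0 lists, 8 being at an unadjusted p under 0.05, while fry, which asks only whether a list moves 1 way, called 20. The smallest were at adjusted p = 0.0824 with an estimated correlation, for stilbene synthase, flavonoids, PR proteins and ethylene. It was 0.0833 for phenylpropanoid entry, 0.0898 for jasmonate biosynthesis and WRKY factors, 0.11 for chitinases and 0.191 for lignin, terpenoids and heat shock. It was 0.255 for antioxidants and for peroxidases and laccases, 0.287 for NB-LRR and 0.456 for photosynthesis.

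The photosynthesis call (adjusted p = 0.0284) was lost without Shine-muscat control replicate 1 (0.139) or Shine-muscat treated replicate 1 (0.0662), and fry did not call that list either (0.0526). The chitinase call (0.0208) was lost without Shine-muscat treated replicate 3 (0.0614). Sugar genes (0.0752) passed without Shine-muscat control replicate 1 (0.0233).

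**Figure D3:**
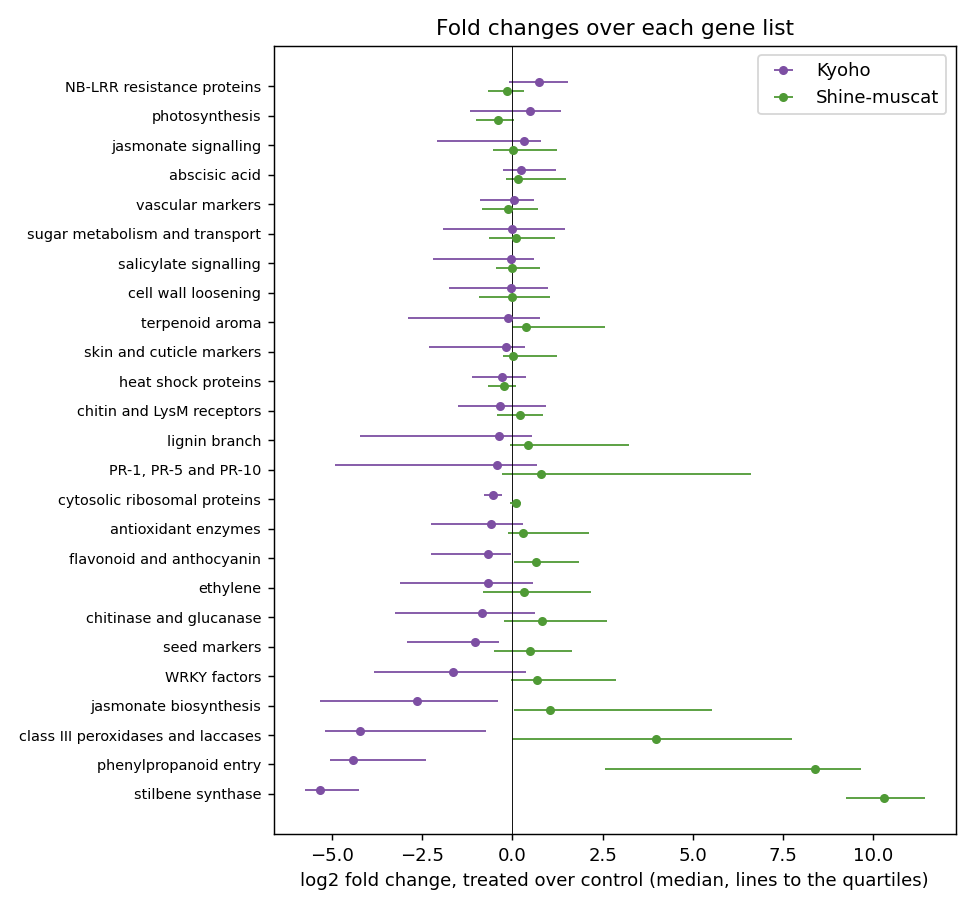
Median log2 fold change of treated over control for each of the 25 gene lists, with lines to the quartiles of its genes, in Kyoho and in Shine-muscat. Stilbene synthase has medians of -5.34 in Kyoho and 10.3 in Shine-muscat, and those of phenylpropanoid entry are -4.41 and 8.39.

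The responses labelled treated over control ran in opposite directions in the cultivars, which share no library. Across the 19530 genes, which are not independent replicates, the fold changes had r = -0.68 (Pearson) and rho = -0.55 (Spearman). Of 5110 genes changed in both cultivars, 4650 (91%) changed in opposite directions and 460 in the same one. Of these, 2776 fell in Kyoho and rose in Shine-muscat, where 1128 would be expected of independent lists (odds ratio 11, 95% interval 10.2 to 12, Fisher's exact test). Another 1874 rose in Kyoho and fell in Shine-muscat, where 849 would be (odds ratio 6.02, interval 5.53 to 6.55). In the same direction, 239 rose in both against 1127 expected and 221 fell in both against 850.

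The difference between the responses, Shine-muscat minus Kyoho, was tested in the same edgeR fit. It was higher in 5582 genes and lower in 5611, among them all 4650 genes with opposite changes. The latter is close to given, since the difference of opposite changes is larger than either change. By p, not by size, the positive differences were led by ethylene-responsive factor 1A, VIT_202s0234g00130 (chromosome 2, 177838 to 178960, difference in log2 fold change 6.41 ± 0.21). Glutamine dumper 2, VIT_214s0083g00670 (chromosome 14, 22722348 to 22722787, difference in log2 fold change 10.32 ± 0.34), and nuclear fusion defective 4, VIT_208s0007g04860 (chromosome 8, 18809103 to 18811961, difference in log2 fold change 12.01 ± 0.38), followed. So did the phosphodiesterase GDPD1, VIT_214s0068g01500 (chromosome 14, 25221282 to 25224483, difference in log2 fold change 7.23 ± 0.26), and the kinase WNK4, VIT_206s0004g07920 (chromosome 6, 8664997 to 8669562, difference in log2 fold change 5.84 ± 0.22). Glutamine dumper 2 was at 46 ± 8.17, 0.701 ± 0.108, 0.768 ± 0.207 and 15.3 ± 3.39 CPM in Kyoho control, Kyoho treated, Shine-muscat control and Shine-muscat treated libraries. By p, the negative differences were led by cinnamoyl-CoA reductase 1, VIT_206s0004g07130 (chromosome 6, 7898099 to 7902334, difference in log2 fold change -2.96 ± 0.15), and an inactive leucine-rich repeat receptor-like kinase, VIT_214s0171g00180 (chromosome 14, 26032697 to 26038645, difference in log2 fold change -4.14 ± 0.21). HVA22-like protein e, VIT_217s0000g01080 (chromosome 17, 756634 to 757963, difference in log2 fold change -3.88 ± 0.2), the auxin response repressor IAA27, VIT_211s0016g03540 (chromosome 11, 2881243 to 2885395, difference in log2 fold change -5.95 ± 0.29), and bHLH71, VIT_202s0012g01450 (chromosome 2, 7638431 to 7641557, difference in log2 fold change -6.11 ± 0.31), followed. IAA27 was at 8.55 ± 1.93, 122 ± 13.3, 209 ± 25.7 and 48.1 ± 11.8 CPM in the same order.

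Of the lists, camera called 12 higher and 1 lower (NB-LRR, 41 of 398 genes higher and 162 lower, or 158 lower adjusted over the list alone) in the difference. Stilbene synthase was higher in 41 of 41 (median 15.82, or 14.52 at the bound) and phenylpropanoid entry in 26 of 29 (median 13.3, or 11.08 at the bound). Without Shine-muscat treated replicate 2 these medians were 15.18 and 12.71. With an estimated correlation camera called 0 lists and 6 were at an unadjusted p under 0.05, while fry called 23. The smallest was adjusted p = 0.12 with an estimated correlation, for jasmonate biosynthesis and ethylene. It was 0.148 for stilbene synthase, phenylpropanoid entry, chitinases and WRKY factors and 0.203 for flavonoids and PR proteins. It was 0.207 for NB-LRR, 0.234 for peroxidases and laccases, 0.24 for lignin, 0.283 for antioxidants and 0.651 for ribosomal proteins. Among lists not called, medians and means differed in sign for jasmonate signalling (-0.3 and 1.12, test directed up) and abscisic acid (-0.11 and 0.97, up). So they did for wall loosening (-0.09 and 1.27, down) and vascular markers (-0.36 and 0.43, down), and heat shock had 0.1 and 0.02 with a test directed down. The heat shock median turned to -0.09 with upper-quartile factors and -0.16 with library totals, and salicylate genes went from 10 higher and 8 lower to 8 and 9 with library totals. With library totals as the only scaling 4505 genes were higher and 7216 lower in the difference, with upper-quartile factors 4830 and 6839, and with limma on log2 FPKM 4092 and 6819. With DESeq2 size factors 5717 were higher and 5434 lower. The all-gene median moved by -0.274 with library totals, -0.231 with FPKM and -0.196 with upper-quartile factors.

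**Figure D4:**
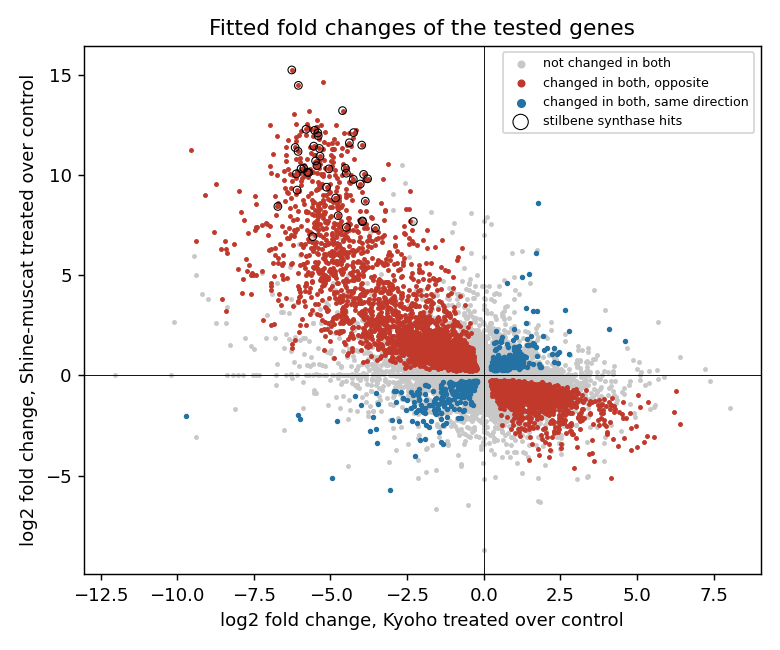
Fitted log2 fold change of treated over control for the 19530 tested genes, Kyoho on the horizontal axis and Shine-muscat on the vertical. Of the genes changed in both, 4650 lie in the quadrants of opposite change and 460 in those of the same change; stilbene synthase genes, which have few or no counts in Shine-muscat control libraries, stand at the upper left.

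Between the control berries, 6887 genes were higher and 7445 lower in Shine-muscat than in Kyoho, 73.4% of those tested. The balance turned to 7649 higher and 6753 lower with upper-quartile factors, 7936 and 6375 with library totals and 6997 and 5398 with limma on log2 FPKM. The largest differences were mostly genes without counts in a group. Pectinesterase 2, VIT_206s0009g02560 (chromosome 6, 15304313 to 15306396), was at least 45600-fold lower in Shine-muscat, from 954 ± 56.8 CPM in Kyoho. Stilbene synthase 6, VIT_216s0100g01150 (chromosome 16, 16643899 to 16645890), was at least 27600-fold lower, from 569 ± 106 CPM. A valencene synthase of terpenoid synthesis, VIT_218s0001g05230 (chromosome 18_random, 4207807 to 4210084), was at least 15100-fold lower, from 319 ± 100 CPM. The isoflavone 2'-hydroxylase hit VIT_207s0129g00800 (chromosome 7, 16015531 to 16017755) was 125000-fold higher in Kyoho (95% counting interval 34600 to 1030000), at least 53100-fold without Shine-muscat control replicate 1, which held its 2 counts, and 82900-fold without replicate 3. Higher in Shine-muscat were a TMV resistance protein N hit, VIT_218s0117g00070 (chromosome 18, 23143168 to 23144116), at least 1020-fold, and transcription factor MYB93, VIT_216s0039g01920 (chromosome 16, 1905332 to 1907861), at least 416-fold. The 2-hydroxyacyl-CoA lyase VIT_205s0124g00510 (chromosome 5, 21098680 to 21109158) was at least 309-fold higher. The DSC1-like protein VIT_218s0117g00080 (chromosome 18, 23148797 to 23151705) was 3610-fold higher (95% counting interval 648 to 143000), with a single Kyoho count. It was 2330-fold without Kyoho control replicate 1, 2350-fold without 2 and at least 847-fold without 3, which held the count.

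Of pigment, aroma and stilbene genes, dihydroflavonol 4-reductase, VIT_218s0001g12800 (chromosome 18, 10907364 to 10910253, log2 difference 1.66 ± 0.14), was higher and leucoanthocyanidin dioxygenase, VIT_202s0025g04720 (chromosome 2, 4282027 to 4284085, log2 difference -6.2 ± 0.19), lower in Shine-muscat control berries. A 1-deoxy-D-xylulose-5-phosphate synthase, VIT_200s0218g00110 (unplaced sequence Un, 14030379 to 14035523, log2 difference 3.68 ± 0.25), was higher and geraniol 8-hydroxylase, VIT_202s0025g04890 (chromosome 2, 4403949 to 4404958, log2 difference -6.18 ± 0.24), lower. Stilbene synthase 1, VIT_216s0100g01070 (chromosome 16, 16525933 to 16527963, log2 difference -14.62 ± 0.82), was lower, at -15.25 without Shine-muscat control replicate 1. The groups of 14713 genes did not overlap, against 10% by chance, and 9047 differed at least 2-fold. The authors' deposited table calls 12692 genes, of which 12269 were called here. The all-gene median moved by 0.19 with library totals, 0.172 with FPKM and 0.128 with upper-quartile factors.

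Between the treated berries, 5300 genes were higher and 4711 lower in Shine-muscat, 51.3% of those tested. The balance turned to 4882 higher and 5452 lower with upper-quartile factors, 4722 and 5473 with library totals and 4043 and 4946 with limma on log2 FPKM. MLP-like protein 31, VIT_201s0011g05150 (chromosome 1, 4790374 to 4792271), was at least 5530-fold lower in Shine-muscat and glutathione S-transferase F12, VIT_204s0079g00690 (chromosome 4, 11504521 to 11507410), at least 1230-fold. The disease resistance protein At4g27190 hit VIT_214s0030g00150 (chromosome 14, 3885629 to 3893034) was at least 470-fold lower. The cytochrome P450 71A1 hit VIT_218s0001g13770 (chromosome 18, 11767436 to 11769613) was 1960-fold higher in Kyoho (95% counting interval 352 to 77600), and at least 435-fold without Shine-muscat treated replicate 2, which held its single count. Higher in Shine-muscat were a disease resistance protein hit, VIT_214s0030g00520 (chromosome 14, 4485583 to 4494395), at least 1240-fold, and a glutathione S-transferase, VIT_217s0000g02930 (chromosome 17, 2705577 to 2706534), at least 1080-fold (610-fold without Shine-muscat treated replicate 2). Accelerated cell death 11, VIT_211s0052g00230 (chromosome 11, 17394682 to 17396073), was at least 832-fold and the TMV resistance protein N hit VIT_218s0117g00070 (chromosome 18, 23143168 to 23144116) at least 504-fold higher.

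Naringenin dioxygenase of flavonoid synthesis, VIT_204s0023g03370 (chromosome 4, 19929438 to 19931447, log2 difference 2.38 ± 0.16), was higher and leucoanthocyanidin dioxygenase, VIT_202s0025g04720 (chromosome 2, 4282027 to 4284085, log2 difference -1.62 ± 0.15), lower in Shine-muscat treated berries. A second geraniol 8-hydroxylase, VIT_202s0012g02340 (chromosome 2, 9295170 to 9300215, log2 difference 5.13 ± 0.36), and stilbene synthase 4, VIT_216s0100g00860 (chromosome 16, 16349897 to 16351446, log2 difference 5.73 ± 0.46), were higher, the latter at 6.84 without Kyoho treated replicate 3. The valencene synthase VIT_218s0001g04780 (chromosome 18_random, 3982831 to 3985305) was 323-fold higher in Kyoho (95% counting interval 89.1 to 2670). The groups of 12002 genes did not overlap, against 10% by chance, and 5295 differed at least 2-fold. The authors' deposited table calls 8495 genes, of which 8171 were called here. Reads of both cultivars were set against 1 set of gene models, and a cultivar's own sequence differences can lower its counts.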

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

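Of the tests here, the splits of the libraries were chosen before the result was seen, while the tests of exchanged labels, exchanged libraries, scaling, skin and carried-over RNA were chosen only afterwards.

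The cultivars differed in their response in 11193 genes by a test of the difference itself, and 4650 genes changed in both cultivars in opposite directions. Median differences on the log2 scale, Shine-muscat minus Kyoho, were 15.82 for stilbene synthase, 13.3 for phenylpropanoid entry and 8.63 for class III peroxidases and laccases as fitted. With genes without counts in a group at their bound they were 14.52, 11.08 and 6.42. Without Shine-muscat treated replicate 1 the fitted median of peroxidases and laccases was 7.83. The medians were 3.91 for jasmonate biosynthesis and 2.85 for WRKY factors (1.94 without Shine-muscat treated replicate 1). They were 1.85 for PR proteins, 1.49 for chitinases and glucanases and 1.02 for lignin. They were 0.94 for ethylene, 0.92 for flavonoids, 0.79 for antioxidant enzymes, 0.61 for ribosomal proteins and -1.09 for NB-LRR receptors. No list passed camera with an estimated correlation, where the smallest adjusted p was 0.12 (6 lists at an unadjusted p under 0.05, and 23 called by fry).

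Single genes with a difference between the cultivars' responses were ethylene-responsive factor 1A (VIT_202s0234g00130, 6.41), glutamine dumper 2 (VIT_214s0083g00670, 10.32) and nuclear fusion defective 4 (VIT_208s0007g04860, 12.01). GDPD1 (VIT_214s0068g01500, 7.23) and WNK4 (VIT_206s0004g07920, 5.84) were also higher in the difference. Lower were cinnamoyl-CoA reductase 1 (VIT_206s0004g07130, -2.96), a receptor-like kinase (VIT_214s0171g00180, -4.14), HVA22-like protein e (VIT_217s0000g01080, -3.88), IAA27 (VIT_211s0016g03540, -5.95) and bHLH71 (VIT_202s0012g01450, -6.11). The difference passed for 57 of the 59 genes that the naming rule gave in Kyoho and for 55 of 58 in Shine-muscat, against 57.3% of all tested genes. The rule chose these genes for a large change or small p in 1 cultivar. That change is part of the difference, so a high share was likely. The difference passed for 9 of 13 in the cultivar comparison of control berries and 4 of 13 in that of treated berries.

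The opposite directions in the cultivars were the first pattern weighed. Exchanged libraries between the cultivars are argued against by 10 genes that were on in 6 libraries and at the floor in the other 6, all parted by cultivar label, with 0 parted crosswise. Scaling moved the median of all genes by at most 0.188 in the treatment comparisons (-0.274 in their difference). The stilbene synthase quartiles lay at -5.76 to -4.26 in Kyoho and 9.24 to 11.43 in Shine-muscat. This argues against scaling as the only source of the stilbene synthase changes. Over all genes in Kyoho, 5672 rose and 5675 fell, against 7191 and 4535 with library totals. A part of scaling in smaller changes therefore stays open. Skin markers had medians of -0.19 (quartiles -2.32 to 0.36) in Kyoho and 0.01 (quartiles -0.27 to 1.23) in Shine-muscat. These quartiles lay apart from those of stilbene synthase, which argues against a different share of skin as the only source of the stilbene synthase changes. Fry called the skin list lower in Kyoho (adjusted p = 1.16e-05) and higher in Shine-muscat (0.000296), so a part of skin in smaller changes stays open. An exchange of the control and treated labels in Kyoho, or in Shine-muscat instead, remains open, since it would only turn the sign of r = -0.68. Infection of control berries, chitosan on some libraries and a true difference between the cultivars also remain open, and none of these was tested.

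The next pattern was the low but nonzero level, in Kyoho treated libraries, of genes strongly expressed in Kyoho control. A fixed share of control RNA carried into the treated libraries would give such genes nearly 1 ratio. The 164 genes used had a mean of at least 10 CPM in Kyoho control and at most 3 counts over Shine-muscat control. Their median ratio was 2.6% (10th percentile 1.24, 90th 16.7), a spread of 13.5-fold between these percentiles, against at most 2.39-fold in 100 simulations. This argues against a fixed share as the only source, and a smaller share beside true expression stays open.

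Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split gave 11347 changed genes in Kyoho (highest other 0), 6805 in Shine-muscat (highest other 1), 14332 between control berries (highest other 0) and 10011 between treated berries (highest other 0), each being the 1 split of 10 with a count as large. By edgeR at unadjusted p under 0.05 the real splits held 12176, 8535, 14698 and 11107 genes. For the difference between the responses, 1 of 100 splits drawn from 200 gave as many genes (11193 against at most 7183 in the others). Most of these splits mix treated and control libraries, which widens the spread within groups. Some keep the real labels of 1 cultivar, among them the split with 7183 genes, which keeps those of Kyoho. The splits do not stand for equal responses in the cultivars, so they cannot decide whether chance gave that count. For the opposite changes 1 of the same 100 gave as many (4650). That test says nothing about direction, since the others gave 0 except the exchange of the labels in 1 cultivar, which turns the 460 changes of the same direction into opposite ones. For the lists, 4 of 10 splits called as many in Kyoho (11, with 11 as the highest other). In Shine-muscat 1 of 10 did (15, with 11 as the highest other). Each of the other splits leaves more treated libraries on 1 side, so part of the treatment difference stays in it. Their counts therefore do not show how many lists camera with the preset correlation calls without a difference.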

How the results depend on the processing

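Library totals as the only scaling was chosen after the result was seen, and the other alternatives were set before the data were examined. Across 153 pairs of a named gene and a comparison, 0 reversed and 0 lost their call under the alternative scalings, tools, filters and replicate block. The naming rule chose them for large changes or small p in the same data, so their calls were likely to hold and say little of other genes. Fits of only the groups compared were run for 143 of the pairs, leaving out the 10 of the difference between responses, and 0 reversed or lost their call. In the leave-one-out fits 0 reversed and 15 calls were lost, each given in the report save that of the ribosomal protein VIT_216s0013g02020 in S (Shine-muscat), at adjusted p = 0.05 without Shine-muscat control replicate 2. Of these pairs, 13 changed less than 2-fold and so fall below the added 2-fold threshold. With an added 2-fold threshold, which by construction passes fewer genes, 5881 genes changed in Kyoho, 3361 in Shine-muscat, 9047 between control berries and 5295 between treated berries, and 2238 changed oppositely in both. With an estimated correlation camera called 2 lists in Kyoho and 0 in Shine-muscat (8 at an unadjusted p under 0.05), where fry called 20 in each. In its mixed form, which asks another question by construction, fry called 25 and 24. Which genes drive the estimated correlations was not examined, and the cause was not tested.

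The DESeq2 Wald test gave 11546 changed genes in Kyoho, 7405 in Shine-muscat, 11521 for the difference between responses, 14441 between control and 10338 between treated berries, and 5042 opposite changes. With DESeq2 size factors these were 11275, 6857, 11151, 14339, 9989 and 4682.

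Leaving out each library in turn gave 10065 to 11161 genes in Kyoho, 5434 to 6401 in Shine-muscat and 10427 to 11328 for the difference. It gave 13558 to 14069 between control and 8751 to 9174 between treated berries, 3812 to 4561 opposite changes, and 10 to 12 lists in Kyoho and 14 to 15 in Shine-muscat.

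With the replicate number as a block, 10712 genes changed in Kyoho, 6071 in Shine-muscat, 10523 for the difference, 14117 between control and 9780 between treated berries, and 4236 oppositely. Camera with the block called 11 and 15 lists; in Kyoho lignin passed (adjusted p = 0.0223) and flavonoids did not (0.0564), and the cause was not tested. The main fit had no such block because the labels do not state that the numbers pair libraries. Residuals of equally numbered libraries correlated at r = -0.07 to 0.07. Depth limits genes without counts in a group, for which folds are bounds.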

Other observations

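All values here were chosen after the results were seen. Further MYB113-type factors, a family that controls anthocyanin synthesis, went with the cultivar. VIT_202s0033g00390 was at 3.98 ± 2.07 CPM in Kyoho control, 6.36 ± 1.33 CPM in Kyoho treated, 0.0202 ± 0.0207 CPM in Shine-muscat control and 0.64 ± 0.215 CPM in Shine-muscat treated libraries. VIT_202s0033g00450 was at 1.1 ± 0.533, 1.85 ± 0.523, 0.0133 ± 0.0115 and 0.044 ± 0.058 CPM in the same order. Of the genes on in 1 cultivar, the tRNA modification enzyme MnmG hit VIT_216s0115g00470 was at 17.4 ± 4.44 and 10.4 ± 2.6 CPM in the Kyoho groups and at 0.0146 ± 0.0127 and 0.00731 ± 0.0127 CPM in the Shine-muscat groups.

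Summed terpenoid genes were at 639.6 ± 114 CPM in Kyoho control, 169.7 ± 11.4 CPM in Kyoho treated, 95.46 ± 7.43 CPM in Shine-muscat control and 222.6 ± 38.4 CPM in Shine-muscat treated libraries. Chitinase and glucanase genes summed to 17490 ± 1390, 6108 ± 295, 6385 ± 982 and 14760 ± 1930 CPM in the same order. Heat shock proteins summed to 4208 ± 48.8, 4608 ± 151, 6323 ± 329 and 5095 ± 104 CPM, and NB-LRR receptors to 1081 ± 30.2, 1413 ± 21.4, 2278 ± 72.3 and 2047 ± 67.5 CPM.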
